A study of Mus musculus with 51 samples.

How the data were processed

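The series holds 51 QuantSeq 3′ tag libraries of mouse gastrocnemius muscle in 10 groups, 1 library per animal, sequenced in 2 batches. Batch 1 holds floxed controls and muscle-specific Bmal1 knockouts on regular chow or high-fat diet. Batch 2 holds, all on high-fat diet, the Bmal1 knockout, the Vhl knockout and the double knockout, each with floxed controls of its own line. Harvest time and the deleted exons are not given in the sources used here.

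Per the labels' protocols, RNA was taken with TRIzol and a column kit, and libraries were made from 300 ng with the Lexogen QuantSeq 3′ forward kit. The deposited counts per gene symbol come, per the submitters' processing notes, from reads checked with FastQC 0.11.4, aligned with STAR 2.6.0 and counted with HTSeq, whose version is not given in the sources used here; the notes name the builds mm10 and GRCm38.p4. The deposited normalized counts, a signal on the scale of a common library size, were made by the authors with edgeR 3.26.8, per the submitters' processing notes. They held 12917 genes in batch 1 and 13893 in batch 2, the genes over 1 CPM in at least 2 libraries.

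Each batch table listed 48321 gene symbols. In batch 2, 27 symbols had been turned into dates, and 48294 symbols could be joined between the batches. No column was left out. Animals bear the numbers of the sample titles; the 4 Bmal1 knockouts of batch 2 are numbered otherwise in the count table, and the labels give the column of each. Depth ran from 6.95 to 14.7 M counts (median 11.5 M in batch 1, 10.9 M in batch 2). Mitochondrial transcripts held 23.3 to 42.5% of counts in batch 1 and 16.6 to 38.8% in batch 2. Correlations of log2 CPM between replicates of a group ran from 0.962 to 0.984 in batch 1 and from 0.970 to 0.991 in batch 2, and no library was a duplicate of another.

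Differences were tested on the deposited counts in R 4.3.3 with edgeR 4.0.16: filterByExpr at its defaults, TMM scaling, robust quasi-likelihood fits and Benjamini-Hochberg adjusted p under 0.05. All groups of a batch were fitted together, which left 12762 genes in batch 1 and 13093 in batch 2. The Bmal1 knockout was also tested over both batches in 1 fit with a batch term (12565 genes). Values are log2 fold changes ± standard error from these fits, or CPM (mean ± SD over animals). A contrast between effects subtracts one knockout effect (knockout against its own control) from another. The contrast of the double knockout with the sum of both single knockouts was added after the data had been seen.

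Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), which ranks members against all other genes of the fit. The correlation between genes was set to 0.01, and each test was repeated with the correlation estimated from the data. P-values of lists were adjusted within a comparison, separately over the fixed lists, the added lists and the lists called in batch 1. The 33 lists (some share genes) were fixed before the data were seen, as were all other choices not named as added. Lists of lymphocyte and keratinocyte markers and of neutrophil and platelet transcripts were added after the data were seen. The genes called higher and those called lower in the Bmal1 knockout of batch 1 on high-fat diet formed 2 further lists, which were tested in batch 2, that is, on other animals. Beside the members of a list that passed among all genes, the numbers higher and lower that passed when adjusted over the list alone (given as alone) are named where they differ.

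The rule for named genes was: Arntl (the gene of BMAL1) and Vhl; the 8 highest and 8 lowest log2 fold changes among genes with adjusted p under 0.05 and an average log2 CPM of at least 2 (5 and 5 for contrasts between effects), leaving out predicted, Riken and mitochondrial genes; and of each list described up to 4 members with the smallest p, which may then be given in the other comparisons. Where no gene passed, the 3 with the smallest p were named. Genes outside this rule are said to be chosen after their values were seen. Positions are from GENCODE M21 on GRCm38.

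On counts simulated from each gene's mean and dispersion, 200 genes at an average log2 CPM of at least 2 were changed by 1.5, 2 or 4-fold. At 2-fold the fits recovered 94.0% of them for Bmal1 loss in batch 1 on high-fat diet, 89.6% on chow, 91.0% and 79.1% for diet in controls and knockouts, 52.2% for diet by genotype, and 100% for Bmal1 loss in batch 2. At 1.5-fold these shares were 65.7%, 20.9%, 56.7%, 43.3%, 7.46% and 79.1%. False calls made up 1.27 to 6.37% of calls over the comparisons.

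Alternatives were DESeq2 1.42.0; limma on the deposited normalized counts; RLE scaling or none; a filter on average expression (log2 CPM of at least 1) or none; fits without the robust option or with the groups of the contrast alone; an adjusted p of 0.01; the replicate number as a block; leaving out each library in turn; and the correlation of camera. Added after the data had been seen were fits without mitochondrial and ribosomal RNA, without 2 chow libraries holding lymphocyte transcripts, without 7 batch 2 libraries holding keratinocyte transcripts, without 2 libraries of the Vhl line that deviate together, and without double knockout 4 and double floxed control 6. The last was meant to leave out keratinocyte transcripts, which that control did not hold, and was kept as run. Without scaling, the median log2 fold change of all genes moved by 0.16 for the Bmal1 knockout of batch 1 on high-fat diet, −0.17 for diet in controls, 0.34 for the Vhl knockout, 0.35 for the double knockout, 0.27 for the double against the Bmal1 knockout effect and 0.11 for both batches joined; elsewhere it moved by under 0.1.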

Results

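The study asked how the muscle clock factor BMAL1 and the hypoxia-inducible factors (HIF) act together on glucose handling of obese mice. The libraries came from gastrocnemius muscle of animals that lack Bmal1, Vhl or both in muscle, and of floxed controls of each line. VHL marks HIF proteins for breakdown, so that its loss keeps HIF active. Batch 1 held, on high-fat diet, 7 controls (10.0 to 14.0 M counts) and 5 Bmal1 knockouts (11.0 to 14.7 M), and on chow 4 controls (8.72 to 12.8 M) and 3 knockouts (9.09 to 11.0 M). Batch 2, all on high-fat diet, held 8 controls (9.91 to 12.8 M) and 4 Bmal1 knockouts (10.2 to 14.0 M), 6 controls (9.51 to 12.1 M) and 4 Vhl knockouts (9.05 to 11.1 M), and 6 controls (9.35 to 14.7 M) and 4 double knockouts (6.95 to 11.2 M).

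Arntl, the gene of BMAL1, and Vhl were looked at first in every group. QuantSeq counts the 3′ end of a transcript, and the deleted part may lie elsewhere, so neither gene checks the labels here. Arntl was at 7.41 ± 1.83 CPM in knockouts and 15.0 ± 2.65 in controls on high-fat diet in batch 1, and at 7.79 ± 2.84 and 14.4 ± 5.40 on chow. In batch 2 Arntl was at 9.27 ± 1.16 CPM in Bmal1 knockouts and 10.9 ± 1.59 in controls, 11.6 ± 2.44 and 16.0 ± 1.31 in the double line, and 12.3 ± 2.19 and 14.8 ± 1.88 in the Vhl line. Its log2 change passed on high-fat diet in batch 1 (−1.02 ± 0.22, adjusted p = 0.0025), in the double knockout (−0.48 ± 0.13, adjusted p = 0.0021) and over both batches (−0.64 ± 0.12, adjusted p = 0.00013). It did not pass for Bmal1 loss on chow (−0.91 ± 0.28, adjusted p = 0.082), for Bmal1 loss in batch 2 (−0.24 ± 0.13, adjusted p = 0.24) or in the Vhl knockout (−0.27 ± 0.13, adjusted p = 0.097). Vhl fell in the Vhl knockout (1.69 ± 0.790 against 3.09 ± 1.30 CPM, −0.85 ± 0.30, adjusted p = 0.022) and in the double knockout (2.61 ± 0.926 against 4.40 ± 0.927 CPM, −0.78 ± 0.26, adjusted p = 0.018). Arntl lies on chromosome 7 from 113207465 to 113314126, and Vhl on chromosome 6 from 113623959 to 113631633.

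Mitochondrial transcripts held 37.7 ± 3.17% of counts in controls and 33.7 ± 3.78% in Bmal1 knockouts on high-fat diet in batch 1, and 28.5 ± 4.08% and 26.0 ± 2.85% on chow. In batch 2 the shares were 31.3 ± 1.31% in controls and 29.5 ± 2.62% in Bmal1 knockouts, 37.1 ± 2.30% and 32.2 ± 3.51% in the Vhl line, and 27.4 ± 2.66% and 19.7 ± 3.06% in the double line.

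**Figure D1:**
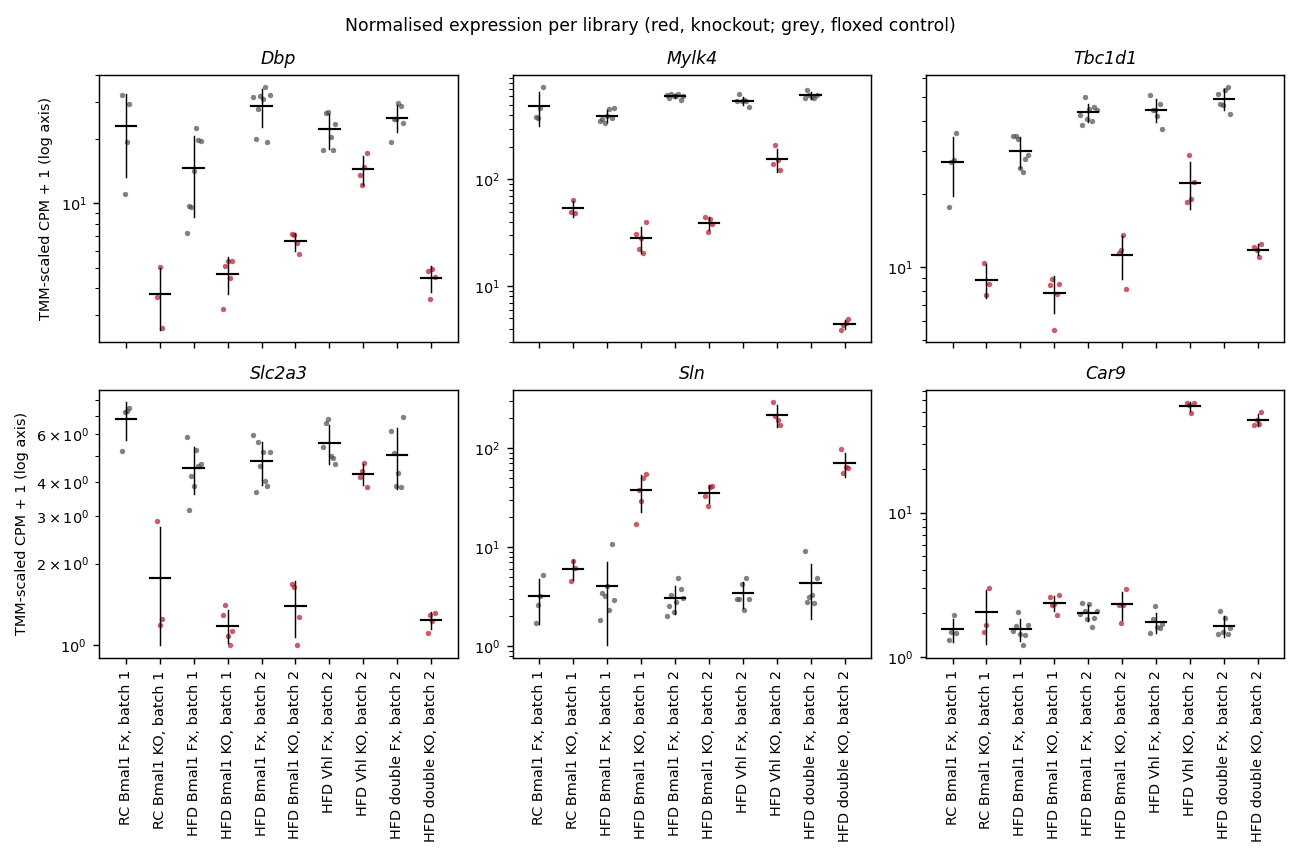
CPM per library (plus 1, log axis) of Dbp, Mylk4, Tbc1d1, Slc2a3, Sln and Car9 in floxed controls (grey) and knockouts (red), with mean ± SD. The 6 genes were picked for display from the named genes after their values had been seen.

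The first question was what loss of Bmal1 does to obese muscle, tested as knockout against control on high-fat diet in batch 1. Clock output fell: Dbp, Nr1d1, Nr1d2, Tef and Hlf, transcription factors that BMAL1 drives through E-boxes, were lower, while Clock, the partner of BMAL1, and Nfil3, a gene that REV-ERB represses, rose. Of genes of sugar uptake and use, Tbc1d1 (a Rab-GTPase activating protein that gates GLUT4 vesicles), Slc2a3 (glucose transporter GLUT3), Hk2 (hexokinase), Pfkm (muscle phosphofructokinase) and Phka1 (a subunit of phosphorylase kinase) fell. Cox5b and Atp5o of the respiratory chain and Acadm, an enzyme of fatty acid oxidation, rose. So did Sln (sarcolipin, a brake on the calcium pump), Cdkn1a (the cell cycle inhibitor p21) and the acetylcholine receptor subunits Chrna1 and Chrnb1. Mylk4, a myosin light chain kinase, and Car3, a carbonic anhydrase of slow muscle, fell.

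Of 12762 genes, 488 were higher and 661 lower in the knockout (1149 changed, 234 of them over 2-fold). At unadjusted p under 0.05 there were 2490, and DESeq2 called 1279. The highest log2 changes were Sln (3.62 ± 0.47, adjusted p = 7.9e-05, 36.7 ± 15.2 CPM in knockouts, 3.08 ± 3.06 in controls), Prss55 (3.55 ± 0.25, adjusted p = 8.5e-13), Cdkn1a (3.10 ± 0.28, adjusted p = 1.3e-06), Dupd1 (2.59 ± 0.15), Ighm (2.55 ± 0.21), Atp8a2 (2.32 ± 0.24), Cpne2 (2.07 ± 0.12) and Gstm7 (2.05 ± 0.24). The lowest were Mylk4 (−3.85 ± 0.22, adjusted p = 1.5e-09, 27.3 ± 7.81 CPM in knockouts, 395 ± 50.3 in controls), Stab2 (−3.58 ± 0.36), Dkk3 (−3.23 ± 0.25), Rasd2 (−3.01 ± 0.16), Car3 (−2.72 ± 0.21), Aebp1 (−2.32 ± 0.14), Cdh4 (−2.08 ± 0.34) and Tbc1d1 (−2.08 ± 0.16, adjusted p = 5.0e-11, 6.83 ± 1.37 against 29.0 ± 4.33 CPM). Slc2a3 was at 0.183 ± 0.166 CPM in knockouts and 3.50 ± 0.885 in controls. Sln lies on chromosome 9 (53850164 to 53854560), Prss55 on chromosome 14 (64075438 to 64090162), Mylk4 on chromosome 13 (32700834 to 32783954), Stab2 on chromosome 10 (86841198 to 87008025) and Tbc1d1 on chromosome 5 (64156305 to 64351486).

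Of 13 E-box clock outputs, 10 fell and 0 rose (10 and 0 adjusted over the list alone, median −1.41, camera adjusted p = 8.6e-12), led by Nr1d2 (−1.78 ± 0.15), Hlf (−1.85 ± 0.17), Tef (−1.12 ± 0.11) and Nr1d1 (−1.51 ± 0.14). Dbp was at 3.69 ± 0.919 CPM in knockouts and 13.7 ± 6.05 in controls. Of 5 core clock activator and REV-ERB-repressed genes, 2 rose and 1 fell (3 and 1 alone, median 0.78, adjusted p = 0.029, adjusted p = 0.33 with an estimated correlation), with Clock at 0.78 ± 0.09. Insulin signalling and glucose uptake genes fell (0 higher, 8 lower, 14 not passing of 22, 2 and 8 alone, median −0.16, adjusted p = 0.0012), led by Tbc1d1, Rab10 (−0.51 ± 0.08) and Irs2 (−0.75 ± 0.14). Glycogen genes fell too (0 higher and 6 lower of 17, 0 and 7 alone, median −0.19, adjusted p = 9.6e-05, adjusted p = 0.18 with an estimated correlation), led by Phka1 (−1.17 ± 0.11), Pgm2 (−0.90 ± 0.11) and Ppp1r3a (−0.71 ± 0.09). In glycolysis 1 gene rose and 6 fell of 22 (1 and 7 alone, median −0.17, adjusted p = 0.0047, adjusted p = 0.20 with an estimated correlation): Pfkm (−0.68 ± 0.09), Slc16a3, a lactate transporter (−0.87 ± 0.12), and Ldha (−0.44 ± 0.09) fell. The 37 HIF-induced genes did not pass (1 higher, 7 lower, 3 and 9 alone, median −0.10, adjusted p = 0.092), with Slc2a3 at −4.18 ± 0.48.

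Respiratory chain and ATP synthase genes rose (29 higher and 0 lower of 55, 46 and 0 alone, median 0.29, camera adjusted p = 3.9e-19, adjusted p = 0.25 with an estimated correlation), led by Cox5b (0.50 ± 0.09) and Atp5o (0.46 ± 0.09). Fatty acid oxidation genes rose (10 higher and 1 lower of 31, 12 and 1 alone, median 0.24, adjusted p = 0.00027, adjusted p = 0.52 with an estimated correlation), with Acadm at 0.64 ± 0.09 and Ucp3, an uncoupling protein, at −0.59 ± 0.10. TCA cycle genes rose (3 higher and 1 lower of 25, 4 and 1 alone, median 0.13, adjusted p = 0.0075, adjusted p = 0.57 with an estimated correlation). Denervation, regeneration and myopathy genes rose (7 higher and 0 lower of 19, 7 and 0 alone, median 0.31, adjusted p = 5.9e-07), led by Chrnb1 (1.28 ± 0.14), Chrna1, Mybph (1.27 ± 0.15) and Myog (1.41 ± 0.21). Integrated stress genes fell (0 higher and 5 lower of 18, 0 and 6 alone, median −0.13, adjusted p = 0.014, adjusted p = 0.18 with an estimated correlation), among them Herpud1 (−0.96 ± 0.09) and Chac1 (−2.02 ± 0.35). Fast fibre genes (1 higher and 4 lower of 15, median −0.22, adjusted p = 0.022) and extracellular matrix genes (2 higher and 0 lower of 27, 1 and 0 alone, median 0.20, adjusted p = 0.014) passed as well, and neither did so with an estimated correlation (adjusted p = 0.52 for each).

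Without scaling, more genes were higher than lower in this comparison (1227 higher, 371 lower), and the fast fibre and core clock lists no longer passed. The call on fast fibre genes was also lost without control 5 (median −0.20) or without knockout 4 (−0.17), that on core clock genes without control 5 (0.75), that on TCA cycle genes without knockout 1 (0.11), and that on matrix genes without control 1 (0.15), 5 (0.14) or 7 (0.15).

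Bmal1 loss was tested in lean muscle (chow, batch 1). As in obese muscle, Dbp, Nr1d1, Nr1d2, Hlf, Mylk4, Tbc1d1, Pfkm and Phka1 fell, and Clock, Cdkn1a, Prss55 (a serine protease) and Chrna1 rose. Cry1 (a clock repressor) and Mt1, a metallothionein, rose, and Odc1, a polyamine enzyme, fell. Sln was at 3.53 to 6.28 CPM in knockouts (controls 0.70 to 4.28).

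On chow, 198 genes were higher and 292 lower (490 changed, 172 over 2-fold, 1743 at unadjusted p under 0.05, DESeq2 590). The highest were Cdkn1a (3.25 ± 0.37, adjusted p = 4.9e-05), Prss55 (3.16 ± 0.31, adjusted p = 7.4e-09) and Mt1 (2.02 ± 0.24). Chrna1 rose by 1.83 ± 0.20. The lowest were Dkk3 (−3.42 ± 0.32, adjusted p = 4.4e-09), Mylk4 (−3.22 ± 0.27, adjusted p = 8.8e-07, 52.7 ± 8.75 against 490 ± 171 CPM), Stab2 (−3.02 ± 0.43), Dbp (−2.99 ± 0.52, adjusted p = 0.0026) and Odc1 (−2.79 ± 0.30). Slc2a3 (−2.94 ± 0.51), Tbc1d1 (−1.72 ± 0.21), Phka1 (−0.75) and Pfkm (−0.62 ± 0.12) fell. Dkk3 lies on chromosome 7 (112116017 to 112159057), Dbp on chromosome 7 (45705088 to 45710203) and Cdkn1a on chromosome 17 (29090976 to 29100727).

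E-box outputs fell on chow (1 higher and 9 lower of 13, 1 and 9 alone, median −1.49, camera adjusted p = 5.0e-13), led by Nr1d2 (−1.67 ± 0.19), Nr1d1 (−1.49 ± 0.18) and Hlf (−1.88 ± 0.22). Denervation genes rose (5 higher and 0 lower of 19, median 0.60, adjusted p = 8.0e-07), among them Mybph (1.47 ± 0.20). Respiratory chain genes rose (5 higher and 0 lower of 55, 27 and 0 alone, median 0.27, adjusted p = 1.9e-15, adjusted p = 0.36 with an estimated correlation). Core clock genes (median 0.68, adjusted p = 0.012, Clock 1.03 ± 0.12), fatty acid oxidation (0.12, adjusted p = 0.0050, Acadm 0.69), TCA cycle (0.19, adjusted p = 0.0011), slow fibre (0.49, adjusted p = 0.0050) and endothelial genes (0.25, adjusted p = 0.012) passed as higher lists, each with adjusted p at or over 0.32 with an estimated correlation. Glycogen (median −0.08, 4 of 17 lower), integrated stress (−0.15), immediate early (−0.54) and macrophage genes (−0.39) passed as lower lists (adjusted p = 0.0099 each), none with an estimated correlation. Adipocyte (−0.92, adjusted p = 0.035 or 0.56 with an estimated correlation) and satellite cell markers (0.35, adjusted p = 0.035 or 0.26) passed as a lower and a higher list, with no member passing. Insulin signalling (−0.08, adjusted p = 0.15), glycolysis (−0.11, adjusted p = 0.24), fast fibre and matrix genes did not pass.

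With 3 knockouts these counts leaned on single animals: without knockout 3 on chow 293 genes passed. Without scaling 319 were higher and 206 lower. Without control 2 and knockout 1, the chow libraries that held lymphocyte transcripts, 364 passed, and fatty acid oxidation (median 0.07, adjusted p = 0.15), slow fibre (0.28, adjusted p = 0.16) and satellite cell genes (0.22, adjusted p = 0.062) no longer did. Leaving out control 2 alone ended the calls on fatty acid oxidation (0.09), slow fibre (0.35), TCA cycle (0.12), macrophage (−0.10) and endothelial genes (0.23). Leaving out knockout 1 ended those on glycogen (−0.13) and core clock genes (0.60), knockout 2 those on macrophage (−0.15), endothelial (0.16) and immediate early genes (−0.51), knockout 3 that on macrophage genes (−0.27), and control 4 that on core clock genes (0.45). Adipocyte markers did not pass without controls 1 (−0.92) or 2 (−0.26) or knockouts 2 (−0.48) or 3 (−0.70), nor satellite cell markers without controls 2 (0.33) or 3 (0.38) or knockouts 2 (0.13) or 3 (0.41).

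Of 12762 genes, 152 were higher on both diets (7.57 by chance), 234 lower on both (15.1 by chance) and 0 opposite (21.4 by chance), and 95.3% of the genes changed on high-fat diet had the same sign on chow. No animal was shared between these comparisons.

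What the high-fat diet did to muscle with an intact clock was tested among the controls of batch 1. Hspa1b, Hspb7 and Bag3 (chaperones), Xirp1, Ankrd1 and Csrp3 (proteins of the strained sarcomere) and Rrad, a GTPase that damps calcium channels, rose. The matrix genes Col4a1 and Timp1 (an inhibitor of matrix proteases) rose, as did Lep, the hormone of fat cells, and the lipid-responsive genes Angptl4 and Fabp3. Klf9, Tsc22d3 and Fbxo32 (a ubiquitin ligase of atrophy), which glucocorticoids induce, fell. Cyp2e1, Cfd (adipsin) and Aqp4, a water channel of fast fibres, fell.

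High-fat diet raised 193 genes and lowered 109 (302 changed, 88 over 2-fold, 1619 at unadjusted p under 0.05, DESeq2 429). The highest were Hspa1b (3.40 ± 0.54, adjusted p = 0.0037), Lep (3.08 ± 0.72, adjusted p = 0.033), Rrad (2.76 ± 0.42, adjusted p = 0.0020), Xirp1 (2.49 ± 0.34, adjusted p = 0.0012), Ankrd1 (2.48 ± 0.47), Csrp3 (2.22 ± 0.42) and Hspa1a (2.08 ± 0.42). Hspa1a and Hspa1b are nearly identical, and reads may be counted for either. The lowest were Cyp2e1 (−3.26 ± 0.58, adjusted p = 0.0072), Cfd (−2.75 ± 0.61, adjusted p = 0.025), Col4a4 (−1.55 ± 0.23, adjusted p = 0.00021) and Aqp4 (−1.45 ± 0.22, adjusted p = 0.00021). Hspa1b lies on chromosome 17 (34956436 to 34959238), Lep on chromosome 6 (29060220 to 29073877), Xirp1 on chromosome 9 (120013755 to 120023598) and Cyp2e1 on chromosome 7 (140763739 to 140774987).

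Heat shock genes rose (7 higher and 0 lower of 16, 10 and 0 alone, median 0.66, camera adjusted p = 4.8e-13), led by Bag3 (0.67 ± 0.11), Hspb7 (1.63 ± 0.30) and Hspb1 (1.07 ± 0.21). Matrix genes rose (9 higher and 0 lower of 27, 13 and 0 alone, median 0.49, adjusted p = 1.4e-10), led by Col4a1 (0.56 ± 0.12), Timp1 (2.63 ± 0.59) and Fbn1 (0.49). Fatty acid oxidation genes rose (5 higher and 0 lower of 31, 13 and 0 alone, median 0.29, adjusted p = 1.1e-05), with Angptl4 at 0.89 ± 0.18 and Fabp3 at 0.97 ± 0.21. Glucocorticoid-induced genes fell (0 higher and 4 lower of 16, 1 and 8 alone, median −0.41, adjusted p = 0.00016), with Klf9 at −0.52 ± 0.11, Tsc22d3 at −0.64 and Fbxo32 at −0.65. Denervation genes rose (6 higher and 1 lower of 19, 7 and 2 alone, median 0.35, adjusted p = 0.0014). Branched-chain amino acid genes (median −0.15, adjusted p = 0.00076, 2 of 23 lower) and E-box clock outputs (median −0.40, adjusted p = 0.00078) fell as lists, with 0 of 13 clock outputs passing alone or among all genes. Further lists passed at adjusted p = 0.020 with medians of −0.16 (glycogen), −0.23 (lipid synthesis), −0.20 (atrophy), 0.22 (integrated stress) and 0.20 (macrophage, Cd68 1.87 ± 0.45), and tendon markers at 0.56 (adjusted p = 0.043) and respiratory chain genes at 0.10 (adjusted p = 0.00078). With an estimated correlation no list passed for diet in controls (adjusted p = 0.19 for heat shock, 0.25 for matrix, 0.32 for fatty acid oxidation and 0.30 for glucocorticoid-induced genes).

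Without scaling 107 genes were higher and 602 lower on the diet, so the split of these counts rests on scaling. Without chow control 3, 181 genes passed, and without chow control 4, 195 did. Lep no longer passed without high-fat controls 2, 4 or 6 or without chow controls 1, 3 or 4 (adjusted p = 0.10 at most), nor did Cfd without high-fat controls 2 or 6 or chow controls 1 or 2 (adjusted p = 0.11 at most). Respiratory chain genes no longer passed without chow control 2 (median 0.02) or without scaling (−0.06). Without chow controls 3 or 4 glycogen (−0.16 and −0.14) and atrophy genes (−0.20 and −0.16) did not pass, nor did integrated stress genes without chow control 3 (0.19) and macrophage markers without chow controls 1 (0.13) or 4 (0.07) or high-fat control 4 (0.18). Lipid synthesis did not pass without high-fat controls 1 (−0.20) or 7 (−0.21) or chow control 2 (−0.04), and tendon markers did not without high-fat controls 3, 4 or 6 or chow controls 2, 3 or 4 (medians from 0.40 to 0.57).

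In muscle without Bmal1 the diet was tested among the knockouts of batch 1. Many of the same genes responded: Lep, Rrad, Xirp1 and Ankrd1 rose, as did the matrix genes Col4a1, Fbn1, Col6a3 and Timp1. The macrophage markers Csf1r, C1qb and Lgals3 rose with them. Chac1, an enzyme that breaks down glutathione, and the glucocorticoid-induced genes Fkbp5, Sesn1, Klf9 and Fbxo32 fell, as did Pfkfb3, which makes the activator of phosphofructokinase, and Tbc1d4, a partner of Tbc1d1 in GLUT4 traffic.

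In knockouts 219 genes rose and 200 fell (419 changed, 113 over 2-fold, 2039 at unadjusted p under 0.05, DESeq2 576). The highest were Lep (4.57 ± 0.92, adjusted p = 0.011), Hp (3.86 ± 0.83, adjusted p = 0.018), Sln (2.87 ± 0.62, adjusted p = 0.018), Rrad (2.43) and Rab15 (2.40 ± 0.37). Xirp1 rose by 1.91 ± 0.38. The lowest were Chac1 (−2.45 ± 0.40, adjusted p = 0.0036), Fkbp5 (−1.65 ± 0.29, adjusted p = 0.0041), Spns2 (−1.63 ± 0.15, adjusted p = 1.3e-08) and Pfkfb3 (−1.58 ± 0.29, adjusted p = 0.0064). Tbc1d4 was at −0.68 ± 0.13, Irs2 at −0.74 and Irs1 at 0.68. Spns2, a sphingolipid transporter, lies on chromosome 11 (72451638 to 72489904).

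Matrix genes rose (10 higher and 0 lower of 27, 15 and 0 alone, median 0.56, camera adjusted p = 4.3e-11), led by Col4a1 (0.81 ± 0.14), Fbn1 (0.83 ± 0.14), Col6a3 (0.80 ± 0.15) and Timp1 (4.05 ± 0.84). Glucocorticoid-induced genes fell (0 higher and 5 lower of 16, 0 and 8 alone, median −0.45, adjusted p = 5.7e-07), led by Sesn1 (−1.42 ± 0.18), Fbxo32 (−1.23 ± 0.19) and Klf9 (−0.72 ± 0.13). Macrophage markers rose (3 higher and 0 lower of 20, 11 and 0 alone, median 0.70, adjusted p = 5.8e-07), with Csf1r at 1.08 ± 0.25 and C1qb at 1.02 ± 0.26, and so did markers of fibro-adipogenic progenitors (median 0.39, adjusted p = 7.7e-05) and heat shock genes (0.44, adjusted p = 1.4e-05). Fatty acid oxidation genes rose (8 higher and 0 lower of 31, 13 and 1 alone, median 0.26, adjusted p = 0.00012, Fabp3 1.45 ± 0.25), and glycogen (0 higher and 5 lower of 17, 0 and 6 alone, median −0.30, adjusted p = 0.0017), glycolysis (−0.12, adjusted p = 0.0077), branched-chain amino acid (−0.23, adjusted p = 5.9e-05) and atrophy genes (−0.22, adjusted p = 0.0018) fell. Adipocyte (median 0.77, adjusted p = 0.010) and erythroid markers (0.58, adjusted p = 0.010) passed with higher medians, 2 and 0 members passing. With an estimated correlation no list passed here (adjusted p = 0.20 for matrix and glucocorticoid-induced genes and 0.22 for macrophage markers).

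Without scaling 118 genes were higher and 316 lower. The count of 419 fell to 132 without chow knockout 3, 272 without high-fat knockout 2 and 264 without high-fat knockout 4. Without chow knockout 3, Lep (adjusted p = 0.076), Xirp1 (0.087), Hp (0.084), Sln (0.098) and Pfkfb3 (0.061) did not pass. Hp and Sln also failed without chow knockouts 1 or 2. Erythroid markers did not pass without chow knockout 1 (median 0.31) or high-fat knockout 1 (0.38), adipocyte markers without chow knockout 2 (0.70), glycolysis genes without chow knockout 2 (−0.14) and atrophy genes without chow knockout 3 (−0.13).

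Between controls and knockouts the diet moved 92 genes up in both (3.31 by chance), 53 down in both (1.71 by chance) and 0 in opposite directions (4.90 by chance). Whether the diet acted differently without Bmal1 was tested as an interaction. Under edgeR 0 genes passed (575 at unadjusted p under 0.05, DESeq2 3, limma 0). The smallest p belonged to Pak1, a kinase of insulin-stimulated glucose uptake (1.05 ± 0.20, adjusted p = 0.069), Sesn1, a stress-induced regulator of TORC1 (−1.28 ± 0.25, adjusted p = 0.069), and Cited2, a HIF-induced brake on HIF (−0.82 ± 0.18, adjusted p = 0.19), none of which passed. Macrophage (median 0.34, camera adjusted p = 0.0018), adipocyte (1.40, adjusted p = 0.0018), erythroid (0.60, adjusted p = 0.0028) and fibro-adipogenic lists (0.28, adjusted p = 0.0018) passed with a more positive diet effect in knockouts. Slow fibre (−0.40, adjusted p = 0.026) and glucocorticoid-induced genes (−0.18, adjusted p = 0.036) had a more negative one. With an estimated correlation adjusted p was 0.56 for fibro-adipogenic markers and 0.71 for the others. Single animals ended these calls too: adipocyte markers did not pass without chow knockout 2 (1.00), erythroid markers without chow knockout 1 (0.36), and macrophage markers without chow control 2 (0.17) or chow knockouts 2 (0.32) or 3 (0.27). Without the 2 chow libraries holding lymphocyte transcripts fibro-adipogenic (0.18), erythroid (0.28) and slow fibre lists (−0.19) did not pass. Slow fibre genes did not pass without high-fat controls 2, 3 or 6, high-fat knockouts 3 or 5, chow controls 2 or 3 or chow knockout 1 (medians from −0.38 to −0.19). Glucocorticoid-induced genes did not without high-fat controls 2, 3 or 6, high-fat knockouts 1, 2 or 3, chow controls 1 or 4 or chow knockout 3 (from −0.22 to −0.13). Without high-fat control 1, 3 genes passed. Without chow knockout 2, 2 did. Without high-fat controls 4 or 5 or high-fat knockout 5, 1 did. Pak1 lies on chromosome 7 (97788541 to 97912381) and Sesn1 on chromosome 10 (41809935 to 41908424).

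Loss of Bmal1 in obese muscle was repeated on other animals in batch 2. Mylk4, Dbp, Nr1d1, Tbc1d1, Slc2a3, Hk2 and Pfkm fell again, and Sln, Cdkn1a, Dupd1 (a dual-specificity phosphatase of muscle) and Chrna1 rose again. HIF-induced genes fell as a list, among them Slc2a3, Mxi1 (a MYC antagonist) and, also in the glycolysis list, Ldha, Slc16a3 and Pfkfb3. Clock and its paralogue Npas2 rose, as did Chrna9, a subunit of acetylcholine receptors, and Tph1, which makes serotonin.

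Of 13093 genes, 909 were higher and 911 lower in the Bmal1 knockout of batch 2 (1820 changed, 295 over 2-fold, 3239 at unadjusted p under 0.05, DESeq2 1924). The highest were Sln (4.05 ± 0.30, adjusted p = 3.1e-11, 34.1 ± 7.36 against 2.06 ± 0.935 CPM), Chrna9 (4.00 ± 0.60, adjusted p = 8.6e-06), Cdkn1a (3.34 ± 0.21, adjusted p = 1.6e-12), Dupd1 (2.70 ± 0.17) and E2f2 (2.29). Tph1 rose by 2.03 ± 0.26. The lowest were Ighg2c (−4.64 ± 0.65), whose reads may belong to similar immunoglobulin genes, Mylk4 (−3.98 ± 0.11, adjusted p = 8.1e-26, 38.2 ± 5.39 against 602 ± 25.0 CPM), Dkk3 (−3.57 ± 0.26), Stab2 (−3.45 ± 0.21), Rasd2 (−3.26 ± 0.15), Car3 (−2.73 ± 0.14) and Chac1 (−2.64 ± 0.37). Tbc1d1 fell by 2.04 ± 0.12 on the log2 scale (10.2 ± 2.27 against 42.2 ± 3.67 CPM), and Dbp by 2.30 ± 0.17 (5.64 ± 0.652 against 27.7 ± 5.86 CPM). Chrna9 lies on chromosome 5 (65934921 to 65977326), Dupd1 on chromosome 14 (21676537 to 21714576), Rasd2 on chromosome 8 (75213944 to 75224113) and Car3 on chromosome 3 (14863512 to 14872523).

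Of the 485 measured genes that had been higher in batch 1, and so were chosen on other animals, 376 were higher and 0 lower in batch 2 (427 and 0 alone, 99.4% positive, median 0.41, camera adjusted p = 2.0e-94 or 6.5e-13 with an estimated correlation). Of the 661 that had been lower, 0 were higher and 486 lower (0 and 553 alone, 98.2% negative, median −0.46, adjusted p = 1.1e-107 or 9.4e-12 with an estimated correlation). No gene was called in opposite directions (82.6 by chance), and the log2 changes of 12454 genes correlated at 0.647.

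E-box outputs fell (1 higher and 11 lower of 13, median −1.08, camera adjusted p = 6.3e-19), led by Nr1d1 (−1.59 ± 0.09), Tef (−1.08 ± 0.07), Nr1d2 (−2.06 ± 0.13) and Hlf (−1.85 ± 0.15). Core clock activator and REV-ERB-repressed genes rose (4 higher and 0 lower of 5, median 0.72, adjusted p = 0.00012): Clock (1.02 ± 0.07), Npas2 (1.77 ± 0.35) and Cry1 (0.72). HIF-induced genes fell (1 higher, 8 lower, 28 not passing of 37, 3 and 8 alone, median −0.17, adjusted p = 0.00074), led by Mxi1 (−0.64 ± 0.08), Slc2a3 (−3.29 ± 0.34), Slc16a3 (−0.59 ± 0.08) and Ldha (−0.52 ± 0.07). Glycogen genes fell (1 higher and 8 lower of 18, 1 and 10 alone, median −0.29, adjusted p = 2.6e-06): Pgm2 (−0.87 ± 0.07), Phka1 (−1.05 ± 0.09) and Ppp1r3a (−0.49). Denervation genes rose (8 higher and 0 lower of 20, median 0.39, adjusted p = 5.3e-08), among them Chrna1 (1.67 ± 0.14). These 5 lists also passed with an estimated correlation (adjusted p = 4.0e-06, 0.010, 0.014, 0.010 and 0.020).

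Glycolysis (1 higher and 6 lower of 23, 1 and 7 alone, median −0.04, camera adjusted p = 0.0055, adjusted p = 0.097 with an estimated correlation, Pfkm −0.67 ± 0.07, Pfkfb3 −1.67 ± 0.20, Hk2 −1.07 ± 0.17) and insulin signalling genes (2 higher and 6 lower of 22, 2 and 7 alone, median −0.13, adjusted p = 0.040, adjusted p = 0.061 with an estimated correlation, Pik3ca 0.50, Akt2 0.46, Akt1 −0.46) passed as lower lists. Integrated stress genes did too (0 higher and 6 lower of 18, median −0.14, adjusted p = 0.00074, adjusted p = 0.055 with an estimated correlation, Herpud1 −1.05 ± 0.07). Respiratory chain genes rose (38 higher and 0 lower of 55, 45 and 0 alone, median 0.23, adjusted p = 6.0e-21, adjusted p = 0.061 with an estimated correlation): Atp5o (0.43 ± 0.05) and Cox5b (0.41 ± 0.05). TCA cycle (7 higher and 1 lower of 25, 12 and 1 alone, median 0.15, adjusted p = 8.5e-05, adjusted p = 0.31 with an estimated correlation) and fatty acid oxidation genes (11 higher and 1 lower of 31, 14 and 1 alone, median 0.17, adjusted p = 0.00056, adjusted p = 0.46 with an estimated correlation, Acadm 0.56 ± 0.06, Plin5 0.77) rose. Fast fibre (1 higher and 5 lower of 15, 1 and 7 alone, median −0.14, adjusted p = 0.011) and macrophage genes (0 higher and 2 lower of 20, 0 and 7 alone, median −0.50, adjusted p = 0.00045) fell, and slow fibre genes rose (1 of 12 higher, median 0.35, adjusted p = 0.042), none of them with an estimated correlation. Keratinocyte markers passed as a higher list (1 of 15 higher, median 1.92, adjusted p = 0.0034), and did not without knockout 6 (0.79) or 7 (1.82).

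Without scaling 1382 genes were higher and 613 lower. Without the 7 keratinocyte-holding libraries (2 were Bmal1 knockouts) 995 genes passed. The call on insulin signalling was lost without control 13 (median −0.10) or knockouts 7 (−0.12) or 9 (−0.11), and that on slow fibre genes without controls 8, 9, 12 or 14 or knockouts 6, 7 or 8 (medians from 0.32 to 0.34).

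With both batches in 1 fit, 1396 genes were higher and 1419 lower of 12565 (2815 changed, 286 over 2-fold, 3904 at unadjusted p under 0.05, DESeq2 2945). Sln (3.83 ± 0.28), Prss55 (3.30 ± 0.16), Cdkn1a (3.22 ± 0.17) and Dupd1 (2.65) were highest. Mylk4 (−3.91 ± 0.10, adjusted p = 3.7e-21), Dkk3 (−3.37 ± 0.17), Rasd2 (−3.11), Car3 (−2.72) and Dbp (−2.07 ± 0.21) were among the lowest. E-box outputs (median −1.15, camera adjusted p = 8.2e-13), glycogen genes (−0.22, adjusted p = 4.2e-06, 1 higher and 11 lower of 17) and HIF-induced genes (−0.12, adjusted p = 0.015, 4 higher and 11 lower of 37) fell and denervation genes rose (0.38, adjusted p = 2.3e-08), in each case also with an estimated correlation (adjusted p = 0.0099, 0.030, 0.0498 and 0.030). Glycolysis (2 higher and 9 lower of 22, −0.12, adjusted p = 0.0032 or 0.051 with an estimated correlation) and insulin signalling genes (2 higher and 9 lower of 21, 2 and 10 alone, −0.13, adjusted p = 0.0029 or 0.051 with an estimated correlation) fell, and respiratory chain genes rose (49 higher and 0 lower of 55, 0.27, adjusted p = 4.6e-23 or 0.11 with an estimated correlation). Without scaling 2692 were higher and 789 lower. Between batches the effect of Bmal1 loss differed for 1 gene, Shisa2, an inhibitor of WNT and FGF signals (0.60 ± 0.10, adjusted p = 0.0075, chromosome 14, 59625308 to 59631660, 716 genes at unadjusted p under 0.05, DESeq2 2). Without knockout 8 of batch 2 it did not pass (0 genes), and without controls 11 or 13 of batch 2 or knockout 5 of batch 1, 2 genes did.

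**Figure D2:**
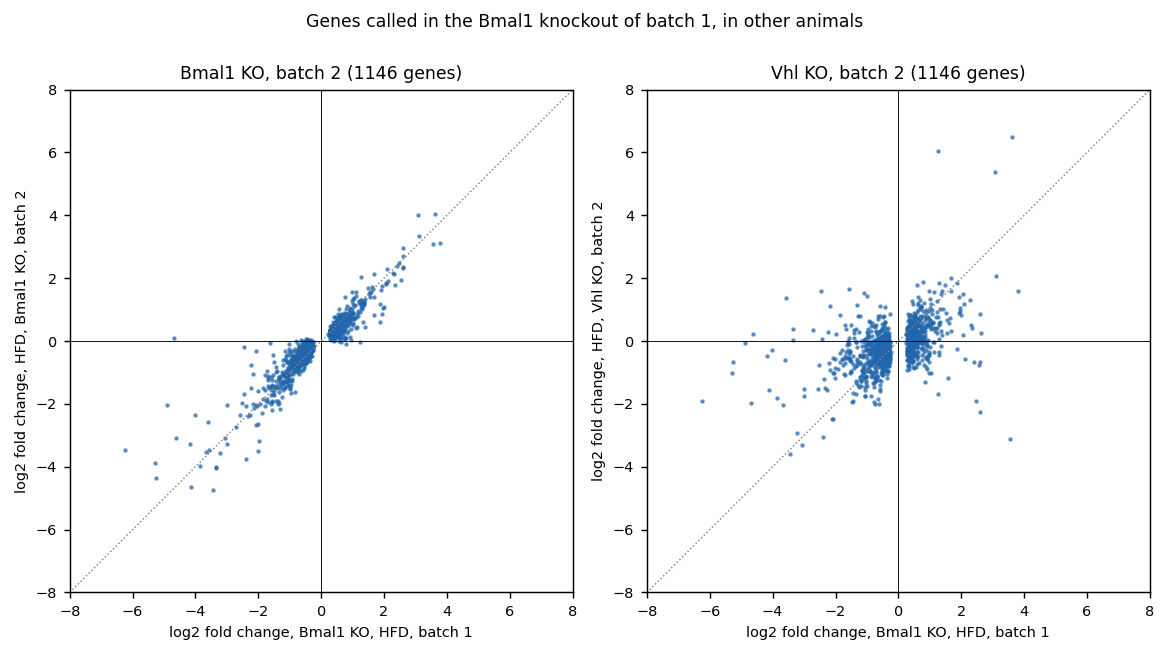
Log2 changes of the genes called in the Bmal1 knockout of batch 1 on high-fat diet against their log2 changes in the Bmal1 knockout (left) and Vhl knockout (right) of batch 2. The dotted line marks equal change.

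Loss of Vhl was tested in batch 2 to see what active HIF does to obese muscle. HIF-induced genes rose: Car9 (carbonic anhydrase IX), Ak4 (adenylate kinase 4), Egln3 and Egln1 (HIF hydroxylases), Ndufa4l2, P4ha1, Bnip3 and Pdk1, which shuts pyruvate out of the TCA cycle. The liver and platelet phosphofructokinases Pfkl and Pfkp and the glucose transporter Slc2a1 rose, while Eno3 (muscle enolase), Slc2a4 (GLUT4), Tbc1d1 and Tbc1d4 fell. Genes of the TCA cycle, of branched-chain amino acid breakdown (Dbt, Bckdhb) and of fast fibres (Myh4, Myl1, Tnnt3) fell. Markers of endothelium (Pecam1, Cdh5), the vessel growth genes Vegfa and Flt1, and globin genes of red cells rose.

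Of 13093 genes, 2320 were higher and 2556 lower in the Vhl knockout (4876 changed, 949 over 2-fold, 5931 at unadjusted p under 0.05, DESeq2 4905). The highest were Sln (6.49 ± 0.32, adjusted p = 2.7e-15, 215 ± 54.3 against 2.41 ± 0.973 CPM), Ak4 (6.39 ± 0.13, adjusted p = 3.0e-36), Car9 (6.17 ± 0.17, adjusted p = 1.3e-32, 53.7 ± 3.96 against 0.742 ± 0.282 CPM), Tph1 (6.06 ± 0.20), Chrna9 (5.36 ± 0.52), Egln3 (4.19 ± 0.13), Ndufa4l2 (4.00 ± 0.18) and Iigp1 (3.36 ± 0.88), an interferon-induced GTPase that did not pass without knockout 2. The lowest were Dkk3 (−2.91 ± 0.28), Igfn1 (−2.62 ± 0.75), Cdh4 (−2.49 ± 0.24), Agbl1 (−2.41) and Mdga1 (−2.16). Cdkn1a rose by 2.09 ± 0.23. Mylk4 was at 155 ± 38.4 CPM in Vhl knockouts and 547 ± 50.7 in controls, and Dbp at 13.5 ± 2.19 and 21.2 ± 4.15. Ak4 lies on chromosome 4 (101419277 to 101466995), Car9 on chromosome 4 (43506966 to 43513729), Tph1 on chromosome 7 (46644641 to 46672537) and Egln3 on chromosome 12 (54178981 to 54203860).

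HIF-induced genes rose (24 higher, 2 lower, 11 not passing of 37, 24 and 3 alone, median 0.63, camera adjusted p = 1.7e-12), led by P4ha1 (2.39 ± 0.09), Egln1 (1.37 ± 0.06), Bnip3 (1.51 ± 0.07) and Pdk1 (1.70 ± 0.09). TCA cycle genes fell, 25 of 25 (median −0.65, adjusted p = 1.3e-18): Idh3b (−0.99 ± 0.08), Sdhb (−0.73 ± 0.06) and Dlat (−0.83 ± 0.07). Branched-chain amino acid genes fell (0 higher and 20 lower of 23, 1 and 21 alone, median −0.69, adjusted p = 1.9e-13): Dbt (−1.83 ± 0.15), Mut (−0.86 ± 0.08) and Bckdhb (−1.45 ± 0.16). Fast fibre genes fell (0 higher and 13 lower of 15, 0 and 14 alone, median −0.52, adjusted p = 2.6e-10): Myl1 (−0.99 ± 0.07), Myh4 (−0.94 ± 0.07) and Tnnt3 (−0.84 ± 0.07). With an estimated correlation these 4 lists passed (adjusted p = 6.5e-06, 0.011, 0.00032 and 0.023). Respiratory chain genes (1 higher and 46 lower of 55, median −0.40, adjusted p = 2.6e-17 or 0.097 with an estimated correlation, Uqcrc2 −0.82 ± 0.06, Cox6a2 −1.07 ± 0.08) and fatty acid oxidation genes (4 higher and 17 lower of 31, median −0.39, adjusted p = 0.00075 or 0.46 with an estimated correlation) fell.

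Endothelial markers rose (13 higher and 0 lower of 14, median 1.01, camera adjusted p = 4.7e-12): Pecam1, Egfl7 (1.25) and Cdh5 (1.17). Angiogenesis genes rose (14 higher and 2 lower of 19, median 0.94, adjusted p = 9.6e-05): Flt1 (1.08 ± 0.07) and Vegfa (1.32 ± 0.12). Erythroid markers rose, 8 of 8 (median 2.35, adjusted p = 2.3e-09): Hbb-bs (2.49 ± 0.19), Hbb-bt (2.55 ± 0.21) and Alas2, which starts haem synthesis (2.20 ± 0.23). The globin genes are similar, and reads may be counted for either. These 3 lists passed with an estimated correlation (adjusted p = 0.00070, 0.011 and 0.037). Macrophage (14 higher and 0 lower of 20, 15 and 0 alone, median 0.67, adjusted p = 0.00045), smooth muscle (6 higher and 1 lower of 10, median 0.75, adjusted p = 0.0012) and matrix genes (11 higher and 2 lower of 27, median 0.33, adjusted p = 0.012) rose, and did not pass with an estimated correlation (adjusted p = 0.44, 0.058 and 0.61). Matrix genes did not pass without knockout 4 (median 0.30).

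Glycolysis genes moved both ways (11 higher and 7 lower of 23, median 0.49, camera adjusted p = 0.089) and did not pass: Pfkl (2.90 ± 0.15), Pfkp (2.39 ± 0.15) and Pkm (0.83 ± 0.06) rose and Eno3 (−0.95 ± 0.07) fell. Insulin signalling genes (6 higher and 8 lower of 22, 7 and 9 alone, median −0.18, adjusted p = 0.21) did not pass either, with Slc2a1 at 1.15 ± 0.15, Slc2a4 at −0.59 ± 0.07, Tbc1d4 at −1.08 ± 0.11 and Tbc1d1 at −1.02 ± 0.11. In glycogen metabolism Phka1 (−1.44 ± 0.09) fell and Ppp1r3b (2.80), which targets a phosphatase to glycogen, rose. Slow fibre genes (7 higher and 1 lower of 12, median 0.76, adjusted p = 0.37, Tnnc1 1.28, Tpm3 1.25) and HIF pathway components (3 higher and 3 lower of 9, median −0.04, mean 0.33, adjusted p = 0.19) did not pass. Of the clock genes, Nr1d1 (−0.62 ± 0.09), Dbp (−0.67 ± 0.16) and Bhlhe41 (−1.32 ± 0.09) fell. Without scaling 5815 genes were higher and 684 lower, so falling lists are relative to the other genes of the library.

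Of the genes lower in the Bmal1 knockout of batch 1, 44 were higher and 385 lower in the Vhl knockout (51 and 402 alone, median −0.38, camera adjusted p = 3.2e-21), and of those higher, 178 were higher and 113 lower (186 and 117 alone, median 0.11, adjusted p = 0.016 or 0.13 with an estimated correlation). Between the Bmal1 and Vhl knockouts of batch 2, 264 genes were higher in both (161 by chance), 470 lower in both (178 by chance) and 303 opposite (339 by chance). Their log2 changes correlated at 0.217.

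Loss of Bmal1 and Vhl together was tested in the double knockout of batch 2. HIF-induced genes rose as in the Vhl knockout (Ak4, Car9, Egln3, Bnip3, P4ha1), and clock outputs fell as in the Bmal1 knockout (Dbp, Nr1d1, Nr1d2, Hlf, Tef). Mylk4 fell below its level in either single knockout, and Chrna9 and Tph1 rose. Cdkn1a, Pfkl, Pfkp, Slc2a1 and Vegfa rose. Tbc1d1, Slc2a4, Mpc1 (the mitochondrial pyruvate carrier) and Nmrk2, a kinase of NAD synthesis, fell.

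In the double knockout 2272 genes were higher and 2366 lower (4638 changed, 1053 over 2-fold, 5782 at unadjusted p under 0.05, DESeq2 4657). The highest were Chrna9 (8.08 ± 0.44, adjusted p = 2.3e-15), Tph1 (6.74 ± 0.19), Ak4 (6.31 ± 0.13, adjusted p = 1.3e-36), Car9 (6.04 ± 0.16, adjusted p = 2.7e-32, 42.8 ± 4.10 against 0.642 ± 0.263 CPM), Sln (4.38 ± 0.30, 69.3 ± 19.0 against 3.30 ± 2.45 CPM), Cdkn1a (4.26 ± 0.24), Egln3 (4.07 ± 0.13) and Ndufa4l2 (3.96 ± 0.18). The lowest were Mylk4 (−7.47 ± 0.15, adjusted p = 6.3e-32, 3.41 ± 0.443 against 613 ± 41.0 CPM), Cdh4 (−3.23 ± 0.25), Rasd2 (−3.14 ± 0.15), Snai3 (−2.99), Dbp (−2.82 ± 0.19, 3.46 ± 0.632 against 24.2 ± 3.61 CPM), Otub2 (−2.70), Nmrk2 (−2.70) and Dkk3 (−2.67 ± 0.26).

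HIF-induced genes rose (24 higher and 5 lower of 37, median 0.73, camera adjusted p = 7.5e-10): Bnip3 (1.65 ± 0.07), P4ha1 (2.11 ± 0.09), Pdk1 (1.62) and Egln1 (1.18). E-box outputs fell (0 higher and 9 lower of 13, median −1.44, adjusted p = 1.4e-09): Nr1d1 (−2.01 ± 0.10), Tef (−1.44 ± 0.08), Hlf (−2.02 ± 0.15) and Nr1d2 (−2.06 ± 0.14). Branched-chain amino acid (0 higher and 21 lower of 23, median −0.49, adjusted p = 8.3e-10, Dbt −1.26 ± 0.14, Bckdhb −1.23 ± 0.14) and fast fibre genes (0 higher and 13 lower of 15, median −0.49, adjusted p = 1.6e-09, Myl1 −1.23 ± 0.07) fell. Endothelial (13 higher and 0 lower of 14, median 0.97, adjusted p = 4.0e-10, Cdh5 1.04 ± 0.10), angiogenesis (12 higher and 2 lower of 19, median 0.95, adjusted p = 7.2e-05, Flt1 1.22 ± 0.07, Vegfa 1.32 ± 0.12) and smooth muscle genes (7 higher and 1 lower of 10, median 0.63, adjusted p = 0.00069) rose. These 7 lists passed with an estimated correlation (adjusted p = 4.1e-05, 0.00055, 0.0013, 0.030, 0.0013, 0.0097 and 0.047).

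TCA cycle genes fell (0 higher and 18 lower of 25, 0 and 22 alone, median −0.37, camera adjusted p = 2.9e-09 or 0.077 with an estimated correlation, Mpc1 −1.49 ± 0.12, Dlat −0.68), and erythroid markers rose, 8 of 8 (median 2.04, adjusted p = 1.3e-07 or 0.067 with an estimated correlation, Hbb-bs 1.98 ± 0.19, Alas2 2.10 ± 0.23). Respiratory chain genes fell (4 higher and 23 lower of 55, 5 and 25 alone, median −0.15, adjusted p = 0.0019 or 0.67 with an estimated correlation), and their median was 0.21 without scaling. Core clock genes (4 higher and 1 lower of 5, median 0.76, adjusted p = 0.023 or 0.077 with an estimated correlation) and denervation genes (10 higher and 5 lower of 20, median 0.53, adjusted p = 0.029 or 0.39 with an estimated correlation, Chrna1 2.69 ± 0.14) rose. Denervation genes did not pass without knockout 1 (0.47) or without scaling. Glycogen (2 higher and 8 lower of 18, median −0.12, adjusted p = 0.025 or 0.19 with an estimated correlation, Phka1 −1.40) and cholesterol genes (0 higher and 5 lower of 19, median −0.25, adjusted p = 0.025 or 0.092 with an estimated correlation) fell. Glycolysis genes did not pass (11 higher and 9 lower of 23, median 0.47, adjusted p = 0.21): Pfkp (3.24 ± 0.14), Pfkl (3.09 ± 0.15) and Pkm (1.09 ± 0.06) rose and Eno3 (−0.96) fell. Tbc1d1 was at −2.16 ± 0.12, Slc2a4 at −0.56 and Slc2a1 at 1.33. Without scaling 6230 genes were higher and 778 lower.

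Of genes lower in the Bmal1 knockout of batch 1, 19 were higher and 520 lower in the double knockout (21 and 534 alone, median −0.62, camera adjusted p = 3.8e-57), and of those higher, 287 were higher and 30 lower (299 and 31 alone, median 0.36, adjusted p = 7.4e-22). Genes shared with the Vhl knockout numbered 1233 higher in both (403 by chance), 1438 lower in both (462 by chance) and 89 opposite (863 by chance). With the Bmal1 knockout of batch 2 there were 434 (158 by chance), 653 (165 by chance) and 127 (322 by chance).

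What Vhl loss adds where Bmal1 is lost was tested as the double knockout effect minus the Bmal1 knockout effect of batch 2. Ak4, Car9, Tph1 and Egln3 were raised by it, together with glycolytic genes such as Pfkp and Ldha. Stab2, a scavenger receptor of sinusoidal endothelium that had fallen with Bmal1, was higher in the double knockout effect. Mylk4, Otub2 (a deubiquitinase) and Mybph (a myosin binding protein) were lower.

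Here 1007 genes were higher and 1184 lower (2191, 516 over 2-fold, 3720 at unadjusted p under 0.05, DESeq2 2298). Ak4 (7.56 ± 0.25), Car9 (5.68 ± 0.31), Stab2 (5.01 ± 0.25), Tph1 (4.71 ± 0.39) and Egln3 (4.57 ± 0.19) were highest. Mylk4 (−3.49 ± 0.16), Otub2 (−2.18), Mybph (−2.07 ± 0.40), Snai3 (−2.01) and Rims4 (−1.98) were lowest. HIF-induced genes (22 higher and 1 lower of 37, 26 and 1 alone, median 0.99, camera adjusted p = 4.0e-21, Bnip3 1.87 ± 0.10, Egln1 1.32 ± 0.08) and glycolysis genes (10 higher and 4 lower of 23, 13 and 4 alone, median 0.62, adjusted p = 6.2e-05, Ldha 1.25 ± 0.10, Pfkp 3.14 ± 0.22) were higher, with Slc2a1 at 1.48 ± 0.22. Endothelial (13 of 14 higher, median 0.92, adjusted p = 5.2e-14), angiogenesis (0.74, adjusted p = 1.9e-05), erythroid (1.97, adjusted p = 3.1e-09) and smooth muscle genes (0.56, adjusted p = 0.00040) were higher too. TCA cycle (0 higher and 22 lower of 25, 0 and 25 alone, median −0.55, adjusted p = 9.1e-20), respiratory chain (0 higher and 39 lower of 55, 0 and 41 alone, −0.39, adjusted p = 2.5e-21), branched-chain amino acid (0 higher and 16 lower of 23, 0 and 19 alone, −0.68, adjusted p = 3.6e-15) and fast fibre genes (0 higher and 10 lower of 15, 0 and 11 alone, −0.36, adjusted p = 5.3e-08) were lower. These 10 lists passed with an estimated correlation (adjusted p from 3.3e-08 to 0.046), while macrophage (0.81, adjusted p = 2.1e-05 or 0.34 with an estimated correlation), matrix (0.24, adjusted p = 0.0062 or 0.58 with an estimated correlation) and glucocorticoid-induced genes (0.19, adjusted p = 0.041 or 0.45 with an estimated correlation) did not. Without scaling 2510 were higher and 294 lower. Without the 7 keratinocyte-holding libraries 1374 passed.

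What Bmal1 loss adds where Vhl is lost was tested as the double knockout effect minus the Vhl knockout effect. Cdkn1a, Dupd1 and Ttll7 (a tubulin-modifying enzyme) were higher. Mylk4, Dbp, Tcap (telethonin, a protein of the Z-disc) and Tbc1d1 were lower, and so was Sln. Slc2a3 and Slc16a3 were lower while Acadm, Sucla2 and Uqcrc2, genes of mitochondrial fuel use, were higher.

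Here 590 genes were higher and 531 lower (1121, 206 over 2-fold, 2908 at unadjusted p under 0.05, DESeq2 1304). Cdkn1a (2.18 ± 0.33), Ighm (2.10), Dupd1 (2.06 ± 0.27), Ttll7 (2.05 ± 0.11) and Atp8a2 (1.95) were highest. Mylk4 (−5.65 ± 0.16), Dbp (−2.15 ± 0.25), Sln (−2.11 ± 0.48), Snai3 (−1.91) and Tcap (−1.79 ± 0.10) were lowest. E-box outputs were lower (1 higher and 8 lower of 13, 1 and 10 alone, median −0.92, camera adjusted p = 8.8e-12 or 0.00020 with an estimated correlation): Nr1d1 (−1.38 ± 0.13), Nr1d2 (−1.76 ± 0.18) and Hlf (−1.65). Tbc1d1 (−1.14 ± 0.16), Slc2a3 (−3.50 ± 0.47) and Slc16a3 (−0.77 ± 0.11) were lower. Respiratory chain (24 higher and 0 lower of 55, 34 and 0 alone, median 0.30, adjusted p = 2.1e-13 or 0.35 with an estimated correlation, Uqcrc2 0.49 ± 0.08) and TCA cycle genes (12 higher and 1 lower of 25, 16 and 1 alone, 0.27, adjusted p = 4.1e-07 or 0.35 with an estimated correlation, Sucla2 0.76 ± 0.08) were higher. So were fatty acid oxidation (11 higher and 0 lower of 31, 14 and 1 alone, 0.41, adjusted p = 4.8e-07 or 0.37 with an estimated correlation, Acadm 0.80 ± 0.10) and core clock genes (3 higher and 0 lower of 5, 0.73, adjusted p = 0.0045 or 0.074 with an estimated correlation). Tcap lies on chromosome 11 (98383811 to 98384953). Without the 7 keratinocyte-holding libraries 605 genes passed.

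**Figure D3:**
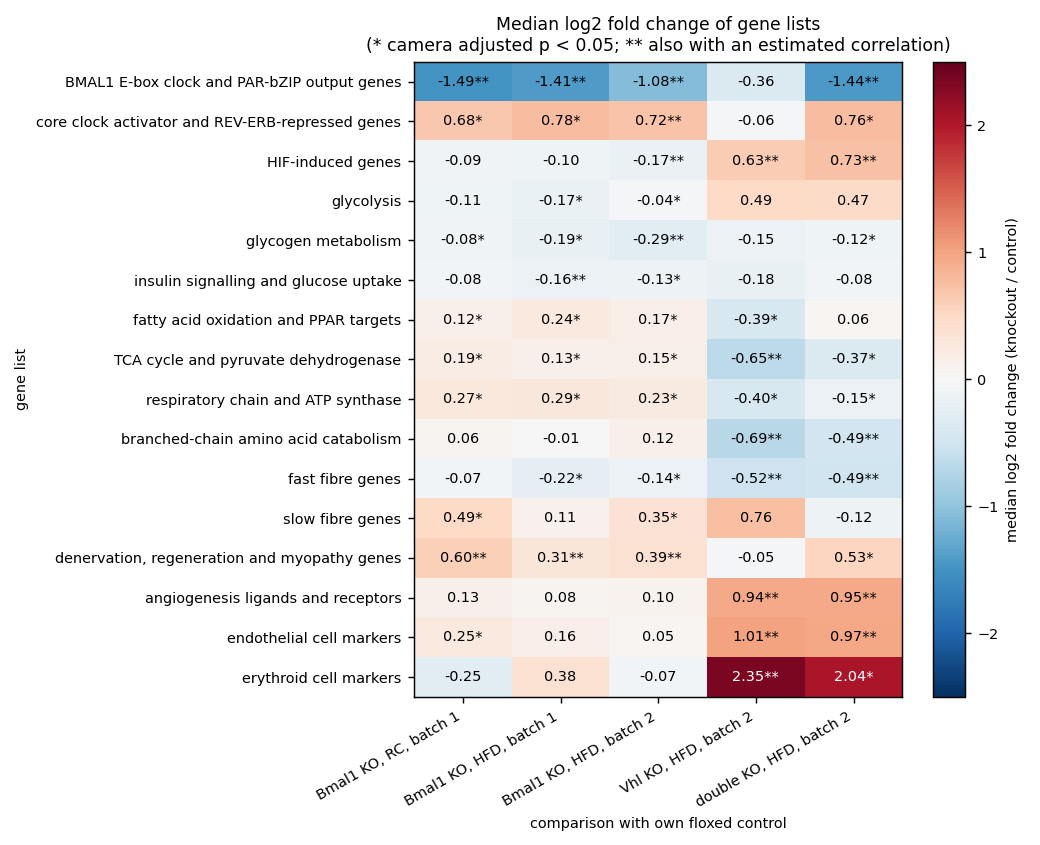
Median log2 change of 16 gene lists in 5 comparisons. Stars mark camera adjusted p under 0.05 with the fixed correlation (1 star) and also with an estimated correlation (2 stars).

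The lists of HIF pathway components, Schwann cell, sex-linked and lymphocyte genes passed in none of these comparisons. HIF pathway components had 0 of 9 members changed in the Bmal1 knockout of batch 1 on high-fat diet (camera adjusted p = 0.81) and 3 higher and 4 lower in the double knockout (adjusted p = 0.32). Schwann cell markers had 0 of 9 changed in the Bmal1 knockout on high-fat diet (adjusted p = 0.91) and a median of 0.65 on chow (adjusted p = 0.056). Sex-linked genes had no member changed in the Bmal1 knockout of batch 1 on high-fat diet (adjusted p = 0.35), the Vhl knockout (adjusted p = 0.73) or the double knockout (adjusted p = 0.99). Lymphocyte markers had a median of 0.54 for Bmal1 loss on chow (adjusted p = 0.79), −2.25 for diet in controls (adjusted p = 0.24) and −3.12 in knockouts (adjusted p = 0.081). Keratinocyte markers, which passed for Bmal1 loss in batch 2, did not in the Vhl (median 2.34, adjusted p = 0.33) or double knockout (2 of 15 higher, median 3.70, adjusted p = 0.19). Neutrophil and platelet transcripts passed for diet in knockouts (1 of 3 higher, median 1.19, adjusted p = 0.031 or 0.12 with an estimated correlation), and did not without high-fat knockout 1 (0.66) or chow knockouts 2 (0.68) or 3 (0.79), nor without mitochondrial and ribosomal RNA (0.63) or the 2 chow libraries holding lymphocyte transcripts (0.85).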

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

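The tests of a lower fibre share and of lymphoid tissue in this part were chosen only after the results were seen. Chance alone marks about 1 in 20 groups in a search of this kind; 144 tests of single libraries (16 measures in 9 groups) marked 10.

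The first pattern is the rise of erythroid transcripts in the Vhl and double knockouts. Whole blood would raise neutrophil and platelet transcripts too, but the erythroid mean rose above theirs by 2.06 on the log2 scale in the Vhl and 1.15 in the double knockout (exact permutation p = 0.00476 in each, the smallest that 210 splits can give, lowest 1.87 without Vhl control 6 and 1.00 without double control 1). Their mean rose by 0.76 in the double knockout (exact permutation p = 0.00476) and 0.32 in the Vhl knockout (exact permutation p = 0.5), where control 6 held 89.1 CPM against 17.3 to 29.8 in other controls and 29.9 to 37.3 in knockouts. This set is low and more red cells alone would do the same, so more blood stays open. A lower share of fibre RNA would raise other cell types alike, but the erythroid mean rose above that of 42 nerve, tendon, fat and fibro-adipogenic genes by 2.51 and 1.89 (endothelial, smooth muscle and macrophage markers, not in this set, rose in the Vhl knockout by medians of 1.01, 0.75 and 0.67), and under 3 scalings the erythroid median was at least 2.35 and 2.04. Red cell precursors or trapped red cells drawn by more vessels stay open as hypotheses.

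The second pattern is the set of genes that moved alike in the Bmal1, Vhl and double knockouts, whose deletion in muscle may rest on 1 shared transgene that the floxed controls lack. Genes next to 1 inserted transgene would cluster, but of 410 genes (401 located) the fullest window of 10 Mb held 9, and 0.875 of 1000 random sets reached as many (median 10, highest 18). An effect of the transgene elsewhere in the genome stays open, since no group carries it alone.

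The third pattern is lymphocyte transcripts in 2 chow libraries of batch 1: the marker sum was 154 CPM in control 2 (2.71 to 4.67 in the others) and 214 in knockout 1. T and B cell transcripts were both up, by at least 29.3-fold over the highest other chow library, so lymphoid tissue taken with the muscle is a candidate source. Where it came from stays open.

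Other libraries stood apart from their group in single measures. Double floxed control 4 held 22.3% mitochondrial transcripts (27.0 to 29.4% in the others), and double knockout 2 held 6.15% of Gm42418 (4.19 to 4.45%). Lymphocyte marker sums were 16.4 CPM in Bmal1 control 12 of batch 2 (5.05 to 9.33) and 34.0 in Vhl knockout 2 (7.66 to 8.98). Keratinocyte marker sums were 129 CPM in double knockout 4 (8.11 to 9.64), 37.3 in Vhl knockout 1 (8.98 to 9.94) and 23.4 in double floxed control 5 (7.24 to 11.4). Endothelial markers averaged 3.75 log2 CPM in Bmal1 knockout 9 of batch 2 (3.89 to 3.91), and Vhl was at 5.73 CPM in high-fat control 4 of batch 1 (2.56 to 3.39).

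Lists on which the effect of Bmal1 loss passed as different between diets with the fixed correlation were slow fibre (−0.40), glucocorticoid-induced (−0.18), macrophage (0.34), adipocyte (1.40), erythroid (0.60) and fibro-adipogenic genes (0.28). With an estimated correlation none passed (adjusted p = 0.56 for fibro-adipogenic and 0.71 for the others). Between batches they were core clock genes (0.30), matrix (−0.24), macrophage (−0.54), adipocyte (−0.44), fibro-adipogenic (−0.18) and keratinocyte genes (1.69), and with an estimated correlation none passed (adjusted p = 0.35 for keratinocyte, 0.48 or 0.54 for the others). The keratinocyte list turned to −2.84 with the replicate block. Of single genes Shisa2 (0.60) differed between batches.

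Of the splits of the animals that were tried, only the true one gave as many genes for Bmal1 loss on high-fat diet in batch 1 (1 of 100 splits, 1149 genes, highest other 232), on chow (1 of 35 splits, 490, highest other 224) and in batch 2 (1 of 100 splits, 1820, highest other 282), and over both batches (1 of 100 splits, 2815, highest other 385). They exclude it for diet in controls (1 of 100 splits; 302, highest other 21) and knockouts (1 of 56 splits; 419, highest other 18), for Vhl loss (1 of 100 splits; 4876, highest other 2742) and the double knockout (1 of 100 splits; 4638, highest other 2379). The same holds for the control groups (1 of 100 splits, 697, highest other 27). For contrasts between effects the splits decide nothing, as they also undo the knockout effects. As large were 1 of 100 splits for the double against the Bmal1 knockout effect (2191, highest other 587) and 1 for the sum of effects (496, highest other 471). For the double against the Vhl knockout effect 2 were (1121, highest other 2737, moving 6 animals), and 5 for the difference between batches (1 gene, highest other 4). What the split of 2737 follows was not tested. For the interaction of diet and Bmal1 loss 0 genes passed under edgeR (575 at unadjusted p under 0.05, DESeq2 3, limma 0), so that 100 of 100 splits give as many by construction and decide nothing (highest other 61).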

How the results depend on the processing

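The alternatives named as added in the methods were chosen after the data had been seen. Calls on named genes moved little between tools and filters. Counts moved more without scaling, under the replicate block and with single libraries left out. Of 1771 values for named genes, 3 turned direction without scaling and none under any other setting; an adjusted p of 0.01 ended 160 of 893 calls, the replicate block 181 of 892 and leaving out the 7 keratinocyte-holding libraries 98 of 643. Of 160 calls on lists, 112 were lost with an estimated correlation. A change of direction was counted only where a value passed in at least 1 of the 2 fits. Except where stated, the cause of a change was not tested.

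At an adjusted p of 0.01, 725 genes passed for Bmal1 loss on high-fat diet and 258 on chow in batch 1, 121 and 157 for diet in controls and knockouts, 1297 and 545 for the double against the Bmal1 and Vhl knockout effects, 287 among controls and 164 against the sum of effects. With only the groups of the contrast fitted, 313 passed for Bmal1 loss on chow. Without a filter 492 passed for diet in controls, 8 for the interaction, 14 between batches and 1445 among controls. Without scaling 709 passed for diet in controls, 1 for the interaction, 7008 for the double knockout, 0 between batches (edgeR; 716 at unadjusted p under 0.05 with scaling, DESeq2 2) and 2764 among controls. DESeq2 called 3 genes for the interaction and 2 between batches. Directions turned without scaling for Bag3 (0.06, adjusted p = 0.063) and Herpud1 (0.05, adjusted p = 0.047) in the Vhl knockout, and for Uty (0.35) and the respiratory chain list (0.21) in the double knockout.

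Replicate numbers did not pair the animals (same-number correlations from −0.213 to 0.204 for Bmal1 loss on high-fat diet in batch 1). With the number as a replicate block, 221 genes passed for Bmal1 loss on chow, 223 for diet in knockouts, 1 for the interaction, 855 and 416 for the double against the Bmal1 and Vhl knockout effects, 1588 over both batches, 0 between batches (edgeR) and 185 against the sum of effects. Under this replicate block the keratinocyte list turned for Bmal1 loss in batch 2 (−2.23), the double against the Bmal1 knockout effect (10.5), between batches (−2.84) and against the sum (6.14), the Schwann cell list for Bmal1 loss in batch 2 (0.73) and between batches (0.71), and the immediate early list between batches (0.48). For Bmal1 loss in batch 2 the block rests on 2 shared numbers of the sample titles, and the other numbering of these knockouts in the count table was not tried. The Vhl and double lines share 4 numbers each, and for the controls the block could not be fitted.

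Without the 7 libraries holding keratinocyte transcripts (sum over 20 CPM; highest of the 25 others 11.4), 995 genes passed for Bmal1 loss in batch 2, 1374 and 605 for the double against the Bmal1 and Vhl knockout effects, 0 between batches (edgeR) and 118 against the sum; 4191 passed for Vhl loss and 4246 for the double knockout. Without double knockout 4 and double floxed control 6, 276 passed against the sum. Without Vhl knockout 2 and Vhl floxed control 6, which deviate together, 948 did. Without the 2 chow libraries holding lymphocyte transcripts, 364 passed for Bmal1 loss on chow, 257 and 429 for diet, and 0 for the interaction (edgeR). Without mitochondrial and ribosomal RNA no count moved by over 1.5 times.

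With single libraries left out, counts ran from 983 to 1133 for Bmal1 loss on high-fat diet, 293 to 502 on chow (lowest without knockout 3), 181 to 308 for diet in controls (lowest without chow control 3; 195 without chow control 4), 132 to 370 for diet in knockouts (lowest without chow knockout 3; 272 and 264 without high-fat knockouts 2 and 4), 0 to 3 for the interaction, 0 to 2 between batches, 1409 to 1801 for Bmal1 loss in batch 2, and 300 to 972 against the sum (without Vhl knockouts 3 and 2). The lymphocyte list ran from −4.28 to 3.23 for Bmal1 loss on chow (lowest without knockout 1, highest without control 2) and from −3.36 to 3.53 for the interaction (lowest without chow control 2, highest without chow knockout 1).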

Other observations

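The tests of this part, the genes shared by the knockouts and the contrast of the double knockout with the sum of both single knockouts, were chosen after the data had been seen, except that of the control groups. Loss of Bmal1 (both batches, high-fat diet), of Vhl and of both moved a common set of muscle genes. Sln, Chrna9 and Cdkn1a rose in all 4 comparisons, and Dkk3, Cdh4, Mylk4 and Rasd2 fell in all 4. Of 12454 genes measured in both batches, 410 passed in all 4 with the same sign: 117 were higher and 293 lower, and 54 changed over 2-fold in each. As 2 of the 4 rest on the same deletion and the double knockout holds both, much overlap is built in. The smallest of the 4 log2 changes was 3.62 for Sln, 3.08 for Chrna9, 2.09 for Cdkn1a and −1.82 for Mylk4. Pla2g5, a phospholipase named after its values were seen, fell alike (−3.05 to −4.38).

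The double knockout effect was then set against the sum of the effects of Bmal1 and Vhl loss in batch 2. Under edgeR 281 genes were above the sum and 215 below it (496, of them 156 over 2-fold; 2199 at unadjusted p under 0.05; DESeq2 658). Sln (−6.15 ± 0.58, adjusted p = 2.3e-07), Rrad (−1.88), E2f2 (−1.81), Klf5 (−1.77 ± 0.22) and Slc15a5 (−1.69) were lowest, and Ighg2c (4.71 ± 1.02), Dkk3 (3.82 ± 0.51), Stab2 (3.63 ± 0.30), Chac1 (2.88 ± 0.58) and Kcnf1 (2.45) highest. Genes lower in the Bmal1 knockout of batch 1 lay above the sum (118 higher and 6 lower; median 0.24, camera adjusted p = 1.6e-17), and those higher lay below it (6 higher and 62 lower; median −0.19, adjusted p = 5.5e-12). Slow fibre (−1.28, adjusted p = 0.012), denervation (−0.44, adjusted p = 0.012), glycogen (0.23, adjusted p = 0.0084), glycolysis (0.21, adjusted p = 0.036) and fast fibre genes (0.24, adjusted p = 0.016) passed as lists, none of them with an estimated correlation. Without scaling 134 were above and 297 below. The count was 118 without the 7 keratinocyte-holding libraries, 185 with the replicate block and 276 without double knockout 4 and double floxed control 6. It was 948 without Vhl knockout 2 and Vhl floxed control 6. It was 972 without Vhl knockout 2 and 300 without Vhl knockout 3, and slow fibre genes did not pass without Vhl knockout 1 (−0.87) or 4 (−1.02). Denervation genes did not without Vhl knockout 4 (−0.40), fast fibre genes without Vhl knockouts 1 (0.21) or 4 (0.15), and glycolysis genes without Bmal1 control 15, Bmal1 knockouts 8 or 9, double knockout 1, Vhl control 5 or Vhl knockouts 1, 3 or 4 (0.16 to 0.19).

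The 3 groups of floxed controls of batch 2 differed in 697 genes (2485 at unadjusted p under 0.05; DESeq2 883), and each knockout was compared with controls of its own line. What sets these groups apart was not tested.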
